A study of Homo sapiens with 33 samples.

How the data were processed

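The deposited table holds expected counts per gene from RSEM 1.3.0 after alignment with STAR 2.5.3a to GRCh38, per the submitters' processing notes. Values were rounded to whole numbers on reading. The share of whole numbers (100%) was counted after that rounding and says nothing of the deposited values. Each of its 33 columns was matched to a sample label. Of 58347 gene identifiers 55720 (95.5%) were in GENCODE 29 with their version and 58084 (99.55%) without it, and 256 gene symbols stood on several identifiers. Mitochondrial genes took 4.24% to 7.57% of the counts and the 10 most abundant genes of a library 5.40% to 8.29%. The first 3 principal components carried 38.4%, 31.1% and 21.3% of the variance, and the fourth 2.11%.

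Genes were tested with edgeR's quasi-likelihood test with BH adjustment (edgeR 4.0.16, limma 3.58.1, R 4.3.3), with TMM scaling, robust dispersions and edgeR's own filter for low counts, in a separate model for each cell line. A gene was called at an adjusted p under 0.05. Log2 fold changes are those of edgeR. Their standard errors were derived as the absolute log2 fold change divided by the square root of the quasi-likelihood F statistic. CPM levels of genes use the TMM-scaled library sizes, and the summed CPM of markers of other cell types per library use the unscaled totals. Principal components and pairing correlations were taken on log values with a prior count of 2. Mean log2 CPM of lists and log2 ratios of replicate 2 used smaller offsets. Differences between the responses of cell lines were tested as interactions over all 24 libraries for interferon gamma and over 21 libraries for crizotinib. The interferon gamma and crizotinib comparisons of EBC1 share the untreated libraries, and so no overlap of these 2 was counted. These choices, the gene lists and the alternatives were set before the data were examined, except those said in the text to be chosen after seeing the data.

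The 27 gene lists were fixed from textbook knowledge and tested with camera at its preset correlation of 0.01. Each was also tested with a correlation estimated from the data and with fry. The first p-value of fry tests whether the genes of a list move in one direction and its mixed p-value whether they move in either direction, and neither compares a list with the other genes. Lists of cholesterol synthesis, lysosome, epithelial, squamous lineage, lung adenocarcinoma lineage and other cell types genes were tested as well and none was called in any comparison. Their adjusted p with HGF in H596 was 0.657, 0.800, 0.783, 0.0863, 0.657 and 0.723. The stress response list was called once, with crizotinib plus HGF against untreated cells (adjusted p = 0.00646, and adjusted p = 0.777 with an estimated correlation).

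Genes named in the text were chosen by a rule. Up to 6 of the largest rises and of the largest falls were named in a comparison if they passed the test, reached 5 CPM in the higher group and had no overlap between the libraries of the groups. From each described list up to 4 genes with the smallest p and up to 2 of opposite direction were named, and a panel (CD274, PDCD1LG2, MET, HGF, JAK1, JAK2, IRF1, B2M, HLA-B and HLA-C among them) was followed throughout. Some genes that this rule selects are not reported here. For interactions 6 genes each way were taken without the condition on overlap. With 3 libraries in each group, 10% of genes without any change would show no overlap between the groups by chance.

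The replicate numbers were checked as a sign of pairing, since the labels do not explain them. After removal of group means, libraries with the same number correlated at 0.146 to 0.374 between untreated and interferon gamma in EBC1 and at 0.145 to 0.387 between untreated and crizotinib. In H596 the correlations were 0.412 to 0.517 for interferon gamma, 0.341 to 0.503 for HGF and 0.419 to 0.568 for crizotinib plus HGF against HGF. A model with the replicate number as a block is therefore reported beside the results of EBC1 and H596 where it changes them. In H1573 the lowest correlation was 0.0984, under the limit of 0.1, and in H1993 the correlations were -0.0450 to 0.000994, so these lines were not treated as paired.

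The alternatives were DESeq2 1.42.0, the size factors of DESeq2 in edgeR, no filter, a filter of 1 CPM in 3 libraries, models of only the 2 groups compared or of all 33 libraries, and each library left out in turn. The code was tested on simulated data, with negative binomial counts drawn from the levels and spread of the control group and the line, in which 200 well-covered genes per comparison were changed. It recovered 93.94% to 100% of 4-fold changes, 68.66% to 97.01% of 2-fold changes and 17.91% to 86.57% of 1.5-fold changes. Of the calls in these simulations, 1 data set per comparison, 3.79% to 15.7% were false, the highest share being in H1993. Overlaps were tested with Fisher's exact test, and splits of the same libraries into other groups served as a check, all 10 within a comparison or 100 drawn with seed 1. Python 3.11.15 with SciPy 1.17.1, NumPy 2.4.6 and matplotlib 3.10.9 was used for labels and figures.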

Results

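Messenger RNA was sequenced from 4 established human lung cancer cell lines that, per the series description, carry changes in MET, the gene of the receptor tyrosine kinase for hepatocyte growth factor (HGF). EBC1 is labelled as a squamous cell carcinoma, and H1573, H1993 and H596 as adenocarcinomas. Interferon gamma, a cytokine of T cells and natural killer cells that signals through JAK1 and JAK2, was given to all 4 lines. EBC1 was also treated with crizotinib, an inhibitor of the MET kinase, and H596 with HGF or with crizotinib plus HGF. The labels give no dose and no time of treatment. The 33 libraries fall into 11 groups of 3 replicates, and the total count per library ranged from 26153788 to 43869781 over 58347 genes. The smallest total was in H1993 with interferon gamma (26153788 to 35786914) and the largest in H596 with HGF (39210254 to 43869781). A floor of 3 counts corresponded to 0.0684 to 0.115 CPM, which are counts scaled to a common library total, and it covers counting error only. Levels are mean CPM ± SD over the 3 replicates of a group. Changes are edgeR's log2 fold changes ± SE, derived from its F statistic, with n = 3 per group. The adjusted p-values measure only the spread between these libraries, since the labels do not say whether the replicates are separate cultures.

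The genes followed in every comparison were placed on GRCh38 with GENCODE 29. CD274 (ENSG00000120217.13), which encodes the PD-1 ligand PD-L1, lies on chromosome 9 from 5450503 to 5470566, and PDCD1LG2 (ENSG00000197646.7), which encodes the PD-1 ligand PD-L2, lies on chromosome 9 from 5510570 to 5571254. JAK2 (ENSG00000096968.13), a kinase bound to the interferon gamma receptor, lies on the same chromosome from 4984390 to 5128183. MET (ENSG00000105976.14) lies on chromosome 7 from 116672390 to 116798386. IRF1 (ENSG00000125347.13), a transcription factor of the interferon response, lies on chromosome 5 from 132481609 to 132490798.

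In EBC1 interferon gamma raised IRF1 from 35.5 ± 1.97 to 1399 ± 149 CPM (log2 fold change 5.31 ± 0.092, adjusted p = 1.35e-12). The steepest rises among abundant genes were those of CXCL9 (11.84 ± 0.37), GBP5 (11.04 ± 0.24), IDO1 (10.24 ± 0.22), CXCL10 (9.25 ± 0.35), APOL4 (8.96 ± 0.42) and TBX21 (8.68 ± 0.20). CXCL9 and CXCL10 are chemokines that attract T cells, GBP5 is a GTPase of cellular defence, and IDO1 degrades tryptophan. CD274 rose from 20.03 ± 2.77 to 84.8 ± 5.48 CPM (2.09 ± 0.098, adjusted p = 1.12e-08), and PDCD1LG2 rose from 2.80 ± 0.27 to 10.6 ± 1.01 CPM (1.93 ± 0.14, adjusted p = 4.40e-07). The steepest falls were those of THBS1 (-2.08 ± 0.12), a matrix glycoprotein, RASD2 (-1.92 ± 0.10), PDE5A (-1.89 ± 0.098), a phosphodiesterase of cyclic GMP, SOCS2 (-1.68 ± 0.10), a brake on cytokine receptors, UNC5C (-1.57 ± 0.14) and HOXC13 (-1.52 ± 0.097).

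Gene groups of the interferon response and of antigen presentation rose together in EBC1. Of 29 measured interferon gamma core genes 28 rose (29 adjusted over the list alone), with a median log2 fold change of 4.56, among them NLRC5 (4.50 ± 0.069), the activator of MHC class I genes, SECTM1 (4.81 ± 0.078) and ICAM1 (6.25 ± 0.11), an adhesion molecule. Of 37 genes stimulated by type I interferon 36 rose (36 adjusted over the list alone), by a median of 2.63, including PARP9 (3.59 ± 0.067), XAF1 (4.19 ± 0.079) and SAMD9L (3.93 ± 0.086). In the MHC class I pathway 18 of 21 genes rose (19 adjusted over the list alone), among them the peptide transporter gene TAP1 (4.69 ± 0.087), the immunoproteasome gene PSMB9 (3.16 ± 0.076), HLA-E (2.97 ± 0.066) and B2M, the light chain of class I molecules (1.12 ± 0.054). HLA-B rose by 1.19 ± 0.081 and HLA-C by 0.66 ± 0.084. All 15 measured MHC class II genes rose (15 adjusted over the list alone), by a median of 3.57, including CD74 (2.07 ± 0.094), the invariant chain, and CIITA (6.21 ± 0.10), the class II transactivator. Of 16 immune checkpoint ligands 12 rose and 1 fell (13 and 1 adjusted over the list alone), with CD47 (1.43 ± 0.044) and BTN3A1 (1.94 ± 0.060) among the rises and VSIR (-0.47 ± 0.14) as the fall. Of 25 cell death genes 21 rose and 2 fell (22 and 2 adjusted over the list alone), with rises of APOL6 (2.81 ± 0.052) and APOL2 (3.42 ± 0.077) and falls of BMF (-0.78 ± 0.070) and BCL2L11 (-0.39 ± 0.073), both pro-apoptotic BCL2 relatives. Of 22 JAK-STAT genes 10 rose and 1 fell (11 and 3 adjusted over the list alone), JAK2 by 2.70 ± 0.086 and IRF9 by 3.22 ± 0.077, whereas JAK1 had a value of -0.07 ± 0.059 (adjusted p = 0.468). Of 20 NF-kappa-B target genes 16 rose (16 adjusted over the list alone), such as SOD2 (2.34 ± 0.074) and the inhibitor gene NFKBIA (1.20 ± 0.064), and of 21 chemokines and cytokines 11 rose and 1 fell (11 and 2 adjusted over the list alone), IL32 by 3.28 ± 0.12 and IL23A by -1.32 ± 0.13. These 9 lists were the only ones called by camera in this comparison, all of them up, and every one kept its call with an estimated correlation (adjusted p = 2.79e-04 for the interferon gamma core and 0.0201 for the chemokines, the highest of the 9). MET itself rose from 4522 ± 136 to 6201 ± 470 CPM (0.47 ± 0.058, adjusted p = 8.21e-05). In all, 3300 of 16416 genes passed the edgeR test, 1926 up and 1374 down, of which 533 rose and 186 fell at least 2-fold, and 5594 passed with the replicate number as a block.

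In H596 interferon gamma raised IRF1 from 78.2 ± 10.1 to 1263 ± 159 CPM (log2 fold change 4.03 ± 0.15, adjusted p = 7.28e-08) and CD274 from 21.3 ± 7.79 to 185.5 ± 62.5 CPM (3.15 ± 0.42, adjusted p = 7.08e-04). PDCD1LG2 rose from 12.4 ± 3.01 to 59.8 ± 19.1 CPM (2.29 ± 0.31, adjusted p = 7.81e-04). CXCL9 had 0 counts in the 3 untreated libraries and 16295 counts with interferon gamma, which makes it at least 6451-fold higher against a floor of 3 counts over the group. The other steepest rises were CXCL11 (9.51 ± 1.11) and CXCL10 (9.34 ± 1.5), APOL4 (9.46 ± 0.49), TRIM40 (7.87 ± 0.33) and SERPING1 (7.49 ± 0.57), the inhibitor of complement C1. Among the steepest falls were SLC29A3 (-1.35 ± 0.20), EPHB3 (-1.31 ± 0.17), an ephrin receptor, PTX3 (-1.15 ± 0.15), BARX2 (-1.14 ± 0.20) and PTCH1 (-1.13 ± 0.20), the hedgehog receptor.

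Of 29 interferon gamma core genes 28 rose in H596 (29 adjusted over the list alone), by a median of 3.95, such as CIITA (7.12 ± 0.31) and ICAM1 (4.47 ± 0.28), and the call held with an estimated correlation (adjusted p = 0.0178). Of 15 MHC class II genes 14 rose (15 adjusted over the list alone), with CTSS (2.28 ± 0.27), a protease that trims the invariant chain, and CD74 (1.55 ± 0.22), and of 26 cell death genes 18 rose (19 adjusted over the list alone), such as the caspase gene CASP10 (2.53 ± 0.18) and MLKL (1.92 ± 0.15), the executor of necroptosis. Both lists had adjusted p = 0.0285 with an estimated correlation. In the MHC class I pathway 10 of 21 genes rose (18 adjusted over the list alone), TAP1 by 3.59 ± 0.38, HLA-E by 2.12 ± 0.21 and B2M by 0.81 ± 0.13. The list had adjusted p = 0.121 with an estimated correlation, and 0.0268 with the replicate block as well, which called 19 members. HLA-B rose by 0.74 ± 0.16 (adjusted p = 0.0141), a call lost without untreated replicate 2 (0.64), without interferon gamma replicate 2 (0.67) and without interferon gamma replicate 3 (0.65). HLA-C had a value of 0.46 ± 0.14 (adjusted p = 0.0748, with the block 0.0236). Of 19 checkpoint ligands 9 rose (10 adjusted over the list alone), CD47 by 1.08 ± 0.13 and TNFRSF14 by 1.27 ± 0.15, with adjusted p = 0.121 with an estimated correlation and 0.0258 with the block as well. Of 22 JAK-STAT genes 7 rose (9 adjusted over the list alone), among them JAK2 (1.73 ± 0.16) and the feedback inhibitors SOCS1 (2.18 ± 0.19) and SOCS3 (1.90 ± 0.30), with adjusted p = 0.121 with an estimated correlation and 0.0349 with the block as well. Of 26 chemokines and cytokines 7 rose (7 up and 1 down adjusted over the list alone), such as IL15 (1.61 ± 0.15), with adjusted p = 0.517 with an estimated correlation and 0.0411 with the block as well. Of 21 NF-kappa-B targets 3 rose (6 adjusted over the list alone), such as NFKBIA (0.86 ± 0.18) and CYLD (1.07 ± 0.15), with adjusted p = 0.707 with an estimated correlation. Mitosis genes had a median of -0.21 with 0 of 30 passing (0 adjusted over the list alone), and the preset correlation called that list down (adjusted p = 0.0357, and adjusted p = 0.926 with an estimated correlation).

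Genes stimulated by type I interferon differed between the replicates of H596 before interferon gamma and were highest in replicate 2. In untreated cells their mean log2 CPM was 5.04, 6.99 and 6.12 in replicates 1, 2 and 3. Of 37 such genes 6 rose with interferon gamma (9 adjusted over the list alone), including SAMD9L (1.82 ± 0.21) and STAT2 (2.12 ± 0.48), and their median was 1.29, with adjusted p = 0.707 with an estimated correlation. With the replicate block 30 of the 37 rose. In the H596 libraries not given interferon gamma, the antiviral gene MX1 had 598.0 to 827.3 CPM in replicate 2 and 55.2 to 288.0 CPM in the other two, while IRF1 in replicate 2 (37.5 to 79.0 CPM) lay within their range (35.5 to 87.8 CPM). Markers of other cell types summed to 466.5 to 565.8 CPM in replicate 3 of H596 and to 209.5 to 318.6 CPM in replicates 1 and 2, in every treatment alike. The edgeR test called 1211 of 17010 genes, 919 up and 292 down, with 469 rising and 59 falling at least 2-fold. It called 3359 with the replicate block, and 431 without the libraries of replicate 2, an alternative chosen after seeing the data.

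In H1573 no change with interferon gamma passed the edgeR test. IRF1 was at 50.4 ± 7.68 CPM untreated and 49.3 ± 8.72 CPM with interferon gamma (log2 fold change -0.03 ± 0.17), and CD274 at 1.43 ± 0.16 and 1.54 ± 0.29 CPM (0.11 ± 0.20). TAP1 (-0.01 ± 0.12), HLA-E (0.02 ± 0.068), B2M (0.07 ± 0.086) and NLRC5 (-0.02 ± 0.17) had values near 0. None of 22 interferon gamma core genes, 36 type I interferon genes, 21 MHC class I genes or 9 MHC class II genes passed, over all genes or adjusted over the list alone, and the core list had a median of 0.02 (adjusted p = 0.365, and 0.987 with an estimated correlation). Of the 16919 genes tested, 0 passed with edgeR, 251 had an unadjusted p under 0.05, and DESeq2 called 3. Camera with its preset correlation called the S-phase list (median 0.04) and the mitosis list (0.04) up and the glycolysis and hypoxia list (-0.07) and the mitochondrially encoded genes (-0.03) down. Their adjusted p = 0.973, 0.772, 0.973 and 0.973 with an estimated correlation.

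In H1993 6 genes passed the test with interferon gamma, all of them up. IRF9, a transcription factor of the interferon response, rose from 9.93 ± 0.99 to 13.8 ± 0.45 CPM (log2 fold change 0.48 ± 0.074, adjusted p = 0.0123), and NLRC5 rose from 9.70 ± 0.030 to 13.3 ± 1.5 CPM (0.46 ± 0.080, adjusted p = 0.0344). PARP14 rose by 0.27 ± 0.038 (adjusted p = 0.0101), APOL6 by 0.26 ± 0.040 (adjusted p = 0.0123), the dynein heavy chain gene DYNC1H1 by 0.14 ± 0.026 (adjusted p = 0.0489) and the pseudogene SLC2A3P1 by 1.66 ± 0.29 (adjusted p = 0.0344), the last named after its value was seen. IRF1 had a value of 0.03 ± 0.049, B2M of 0.00 ± 0.029 and CD274 of -0.04 ± 0.10 (5.76 ± 0.55 CPM untreated and 5.58 ± 0.51 CPM treated). Of 16 interferon gamma core genes 3 rose (5 adjusted over the list alone), of 29 type I interferon genes 1 rose (4 up and 1 down adjusted over the list alone) and of 21 MHC class I genes 1 rose (4 adjusted over the list alone). Their medians were 0.11, 0.07 and 0.02. These lists were called up with the preset correlation (adjusted p = 1.36e-06, 3.70e-05 and 3.53e-04) and not with an estimated one (adjusted p = 0.138, 0.138 and 0.153 with an estimated correlation). Of 15488 genes 945 had an unadjusted p under 0.05, DESeq2 called 13, and leaving out the low-count filter gave 85. The count was 11 without untreated replicate 1, 2 without interferon gamma replicate 2, 3 without untreated replicate 3 and 41 without interferon gamma replicate 3.

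The response to interferon gamma differed between the lines. Across the 24 libraries 1609 of 19541 genes passed a test of any difference between the 4 responses, among them CD274 (adjusted p = 3.82e-06), IRF1 (2.79e-15), JAK2 (2.27e-08), B2M (2.34e-07), HLA-B (3.84e-06), HLA-C (0.0130) and MET (0.0276). PDCD1LG2 (adjusted p = 0.167) and JAK1 (0.282) did not pass. The response of H1573 was lower than that of EBC1 for IRF1 (-5.33 on the log2 scale), JAK2 (-2.73 ± 0.24) and CD274 (-1.98 ± 0.43, adjusted p = 0.00570), and higher for THBS1 (2.09 ± 0.45) and PDE5A (1.96 ± 0.24), which fell in EBC1. In that contrast 281 genes had a higher and 802 a lower response. The response of H1993 was lower than that of EBC1 for IRF1 (-5.27), CD274 (-2.12 ± 0.34, adjusted p = 3.52e-04), NNMT (-6.82 ± 0.64), a methyltransferase of nicotinamide, and the collagen gene COL4A1 (-6.71 ± 0.65), with 298 genes higher and 675 lower. Between H1573 and H1993 0 genes differed with edgeR, 248 had an unadjusted p under 0.05, and DESeq2 called 0. H596 and EBC1 differed in 391 genes, 207 higher and 184 lower in H596, and in 1640 with the replicate block. CX3CL1 (4.51 ± 0.72), a membrane-bound chemokine, TCAF2 (3.07 ± 0.29), DGKG (2.36 ± 0.24) and INPP1 (2.25 ± 0.19) responded more in H596. COL4A1 (-6.96 ± 0.48), NNMT (-4.96 ± 0.74), BST2 (-4.85 ± 0.68), which tethers virus particles to the cell surface, OAS2 (-4.82 ± 0.74) and GBP5 (-4.77 ± 0.60) responded less. As a list, type I interferon genes started higher in untreated H596 (mean log2 CPM 5.04 to 6.99 per library) than in EBC1 (3.50 to 3.57). With interferon gamma they were also higher in H596 (7.04 to 8.17) than in EBC1 (5.76 to 5.99). For CD274 the difference in response between H596 and EBC1 was 1.04 ± 0.30 (adjusted p = 0.0964, with the block 0.00174). H596 exceeded H1993 in 724 genes and lay below it in 300, with CD274 at 3.16 ± 0.34, and H1573 exceeded H596 in 262 and lay below it in 817, with CD274 at -3.03 ± 0.43.

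**Figure D1:**
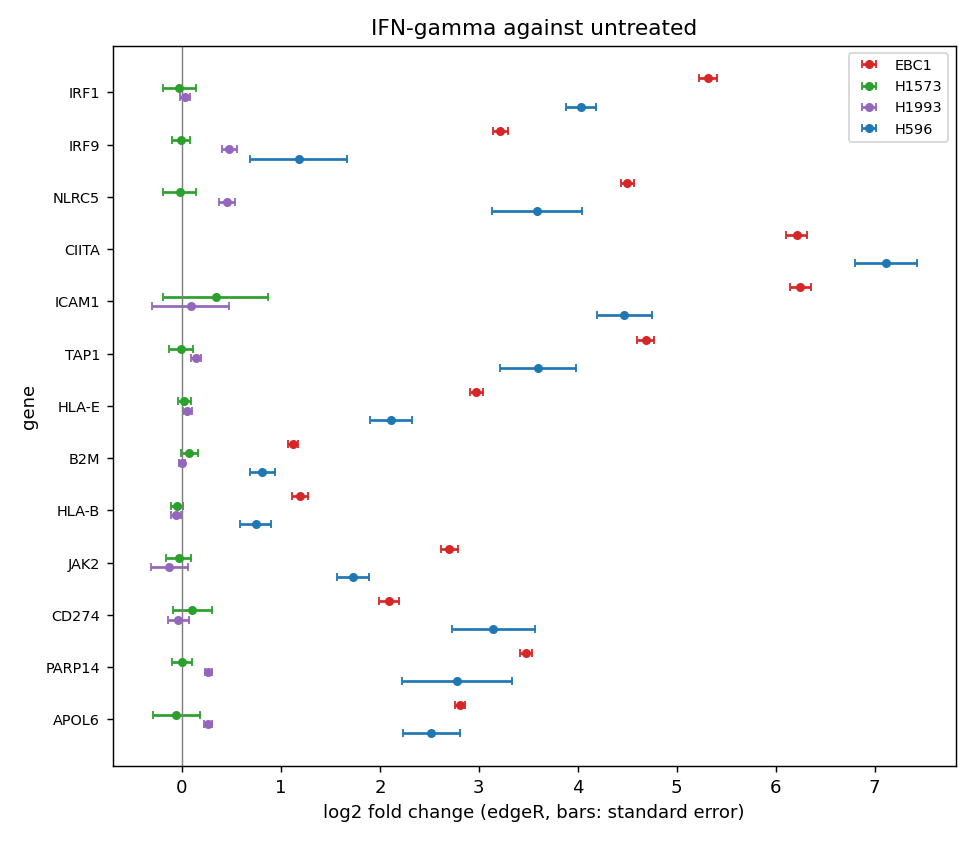
Log2 fold change with interferon gamma against untreated (horizontal axis) for 13 genes of the interferon response and antigen presentation in EBC1, H1573, H1993 and H596, where points are edgeR estimates and bars their standard errors, n = 3 per group. A gene too low to be tested in a line has no point there. IRF1 was at 5.31 in EBC1 and 4.03 in H596, against -0.03 in H1573 and 0.03 in H1993.

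EBC1 and H596 shared much of their response. Of 15081 genes tested in both lines, 630 rose in both (1857 and 824 rose in each), where independent calls would share 101.5, and 131 fell in both (1282 and 244 in each), where independent calls would share 20.7 (Fisher's exact test, 1-sided, p = 9.42e-76 for the falls). Only 4 genes that rose in EBC1 fell in H596, and 7 that fell in EBC1 rose in H596. Among genes changed at least 2-fold, 254 rose in both lines and 7 fell in both. IRF1, CIITA, ICAM1, TAP1, HLA-E, CD274 and CXCL10 were among the genes called up in both. With the replicate block, chosen after seeing the data, 1257 rose and 701 fell in both. Of the 6 genes that rose in H1993, 5 rose in EBC1, where 0.708 was expected (1-sided exact p = 1.23e-04), and 3 rose in H596. With DESeq2, whose own filter left 769 genes with an adjusted p in both lines, the overlap with EBC1 did not pass (4 of 10 genes, 1.83 expected, 1-sided exact p = 0.0921), and at 2-fold or more 0 genes were shared (p = 1 by the same exact test). No gene rose in all 4 lines, as edgeR called 0 in H1573.

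Crizotinib in EBC1 lowered the transcripts that report signalling from MET to the kinase ERK. SPRY4, a feedback inhibitor of receptor kinases, fell from 21.4 CPM to 0.291 CPM (log2 fold change -6.17 ± 0.15, adjusted p = 9.64e-11), DUSP6, a phosphatase of ERK, from 62.4 to 1.45 CPM (-5.41 ± 0.11), and ETV5, a transcription factor, from 54.8 to 4.26 CPM (-3.68 ± 0.080). Further steep falls were ANGPTL4 (-5.68 ± 0.15), an inhibitor of lipoprotein lipase, EGR1 (-5.23 ± 0.69), an immediate early gene, and TNS4 (-4.97 ± 0.27), a focal adhesion protein. The steepest rises were ELF3 (2.29 ± 0.11), an epithelial transcription factor, SPTSSB (2.27 ± 0.17), METTL7A (2.15 ± 0.24), SLC5A3 (1.90 ± 0.10), an inositol transporter, SLC2A12 (1.83 ± 0.13) and PDK4 (1.79 ± 0.093), which restrains pyruvate oxidation. CD274 fell from 20.03 ± 2.77 to 4.54 ± 0.47 CPM (-2.14 ± 0.11, adjusted p = 1.14e-07) and PDCD1LG2 from 2.80 ± 0.27 to 0.307 ± 0.066 CPM (-3.16 ± 0.19, adjusted p = 2.69e-07). MET fell from 4522 ± 136 to 3015 ± 64.9 CPM (-0.58 ± 0.058).

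Of 24 genes of ERK output 22 fell with crizotinib in EBC1 (22 adjusted over the list alone) and none rose, by a median of -2.04, cyclin D1 (CCND1) by -2.45 ± 0.053 (adjusted p = 2.71e-04 for the list with an estimated correlation). Of 22 genes of invasive growth 16 fell (18 adjusted over the list alone), such as the urokinase gene PLAU (-2.20 ± 0.051) and its receptor gene PLAUR (-1.59 ± 0.087), and the call held with an estimated correlation (adjusted p = 0.00757). All 26 genes of ribosome biogenesis and MYC fell (26 adjusted over the list alone), MYC by -1.25 ± 0.057 and NIP7 by -0.99 ± 0.052, with adjusted p = 0.0196 with an estimated correlation and 0.0524 with the replicate block as well. Of 25 receptor kinase and ligand genes 6 rose and 13 fell (6 and 13 adjusted over the list alone). The growth factor genes HBEGF (-3.27 ± 0.15), VEGFA (-1.69 ± 0.059) and TGFA (-0.98 ± 0.058) fell, and the receptor genes ERBB3 (1.28 ± 0.073) and INSR (1.48 ± 0.089) rose (adjusted p = 0.171 for the list with an estimated correlation). Of 28 growth arrest and FOXO target genes 18 rose and 2 fell (19 and 2 adjusted over the list alone), with SESN3 (1.62 ± 0.12) and BCL6 (1.14 ± 0.069) up and KLF4 (-0.47 ± 0.10) and KLF6 (-0.73 ± 0.13) down, and adjusted p = 0.166 with an estimated correlation. Of 21 chemokines and cytokines 2 rose and 10 fell (2 and 11 adjusted over the list alone), LIF by -1.67 ± 0.12 and IL23A by -1.995 ± 0.13, with adjusted p = 0.279 with an estimated correlation.

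Cell death genes went both ways with crizotinib in EBC1. Of 25 genes 5 rose and 9 fell (7 and 9 adjusted over the list alone). The survival genes BCL2L1 (-1.76 ± 0.049) and MCL1 (-1.28 ± 0.045) and the TRAIL receptor gene TNFRSF10A (-2.03 ± 0.072) fell, while the pro-apoptotic genes BMF (1.41 ± 0.068) and BCL2L11 (0.90 ± 0.069) rose. The list had a median of -0.01 and was called down, with adjusted p = 0.410 with an estimated correlation. Of 16 checkpoint ligands 3 rose and 5 fell (3 and 5 adjusted over the list alone), with PVR (-1.13 ± 0.045) down and BTN3A1 (0.66 ± 0.059) up. That list was called down with the preset correlation (adjusted p = 0.0356, and 0.114 with the block), with adjusted p = 0.412 with an estimated correlation. Replication histone genes rose in 4 of 8 (4 adjusted over the list alone), such as HIST1H2BD (0.47 ± 0.058), with adjusted p = 0.524 with an estimated correlation. Of 30 mitosis genes 8 rose and 1 fell (8 and 1 adjusted over the list alone) and of 30 S-phase genes 7 fell (7 adjusted over the list alone), neither list being called (adjusted p = 0.0713 and 0.257). Interferon gamma core genes split into 4 rises, such as GBP2 (0.83 ± 0.094), and 6 falls, such as CIITA (-0.94 ± 0.11), over 29 genes (4 and 6 adjusted over the list alone). Their median was 0.02, their mean was -0.17, and camera gave the direction down (adjusted p = 0.419). IRF1 had a value of -0.11 ± 0.082 and B2M of 0.03 ± 0.053, and JAK1 rose by 0.41 ± 0.059. The test called 5355 of 16416 genes, 2471 up and 2884 down, of which 285 rose and 344 fell at least 2-fold. With the replicate block 7741 genes passed, 3791 up and 3950 down.

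HGF in H596 raised genes of ERK output, of invasive growth and of ribosome biogenesis. SPRY4 rose from 11.5 to 48.1 CPM (log2 fold change 2.05 ± 0.34, adjusted p = 0.0111), FOSL1, a subunit of AP-1, from 188.0 to 561.4 CPM (1.56 ± 0.17, adjusted p = 0.00333) and the growth factor gene HBEGF from 61.7 to 241.5 CPM (1.95 ± 0.42, adjusted p = 0.0332). The other steepest rises were ESM1 (3.03 ± 0.50), a proteoglycan of endothelium, IL1RL1 (2.15 ± 0.38), the receptor of interleukin 33, PLEKHG4B (1.91 ± 0.29) and CD274. CD274 rose from 21.3 ± 7.79 to 85.6 ± 34.7 CPM (1.99 ± 0.40, adjusted p = 0.0242, with the block 1.09e-05). That call without the block was lost without untreated replicate 1 (2.04), 2 (2.24) or 3 (1.73) and without HGF replicate 1 (2.11) or 2 (1.62). The steepest falls were HIST2H4B (-3.49 ± 0.81), VAV3 (-2.72 ± 0.56), ATOH8 (-1.99 ± 0.36), KLHL24 (-1.64 ± 0.22), FGD3 (-1.52 ± 0.24) and SOX2 (-1.41 ± 0.21), a stem cell and squamous lineage factor. IRF1 fell from 78.2 ± 10.1 to 39.7 ± 5.60 CPM (-0.998 ± 0.14, adjusted p = 0.00532) and CIITA from 1.40 to 0.350 CPM (-2.01 ± 0.38, adjusted p = 0.0192), whereas MET had a value of 0.19 ± 0.12.

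Of 24 ERK output genes 8 rose with HGF (18 up and 1 down adjusted over the list alone), such as SPRY2 (1.20 ± 0.20) and EPHA2 (0.91 ± 0.17), and the list kept its call with an estimated correlation (adjusted p = 0.0257). Of 25 genes of invasive growth 7 rose (16 adjusted over the list alone), PLAU by 1.14 ± 0.24, PLAUR by 1.18 ± 0.17 and ITGA2 by 1.52 ± 0.31, with adjusted p = 0.0164 with an estimated correlation and 0.0600 with the block as well. Of 26 ribosome biogenesis genes 5 rose (9 adjusted over the list alone), such as NIP7 (0.47 ± 0.078) and NOP2 (0.40 ± 0.072), with adjusted p = 0.0257 with an estimated correlation and 0.119 with the block as well. Chemokines and cytokines had 2 rises and 1 fall among 26 (8 and 2 adjusted over the list alone), LIF by 1.53 ± 0.19 and IL15 by -0.90 ± 0.15 (adjusted p = 0.607 for the list with an estimated correlation). Of 26 receptor kinase and ligand genes 3 rose and 1 fell (8 and 3 adjusted over the list alone), ERRFI1 by 1.38 ± 0.24, TGFA by 1.34 ± 0.26 and FGFR3 by -0.60 ± 0.11 (adjusted p = 0.733 with an estimated correlation). Of 29 growth arrest and FOXO genes 2 rose and 2 fell (4 and 9 adjusted over the list alone), CDKN1A by 1.08 ± 0.19 and SESN3 by -1.29 ± 0.16 (adjusted p = 0.633 with an estimated correlation). Mitosis genes had a median of -0.33 and 0 of 30 passed (0 adjusted over the list alone, 14 down with the block), with adjusted p = 0.868 with an estimated correlation. The NF-kappa-B, mesenchymal and glycolysis lists were called up with the preset correlation, with 1, 2 and 1 members up, and had adjusted p = 0.868, 0.633 and 0.604 with an estimated correlation. Interferon gamma core genes had 2 rises and 2 falls among 29 (2 and 2 adjusted over the list alone), with a median of 0.03, a mean of 0.08 and a camera direction of down (adjusted p = 0.987). The test called 469 of 17010 genes, 306 up and 163 down, of which 97 rose and 41 fell at least 2-fold. It called 3340 with the replicate block, DESeq2 called 1188, and leaving out 1 of the 6 libraries at a time gave 90 to 254.

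Crizotinib given with HGF moved the HGF-responsive genes of H596 back toward their untreated levels. Against HGF alone, FOSL1 fell from 561.4 to 240.9 CPM (log2 fold change -1.21 ± 0.17, adjusted p = 0.0259), LIF, a cytokine of the interleukin 6 family, from 44.7 to 19.0 CPM (-1.23 ± 0.18, adjusted p = 0.0287) and ESM1 from 13.2 to 1.95 CPM (-2.75 ± 0.49, adjusted p = 0.0405). CCDC71L (-1.27 ± 0.19), PTX3 (-1.18 ± 0.14), a soluble pattern recognition protein, and FAM110C (-1.16 ± 0.16) fell as well. Among the steepest rises were SOX2 (1.17 ± 0.21), KLHL24 (1.16 ± 0.22), SESN3 (1.04 ± 0.16), SRGAP3 (0.97 ± 0.17) and RAB30 (0.91 ± 0.16). IRF1 rose from 39.7 ± 5.60 to 68.9 ± 4.99 CPM (0.81 ± 0.14, adjusted p = 0.0386). CD274 was at 85.6 ± 34.7 CPM with HGF and 29.8 ± 13.1 CPM with crizotinib plus HGF (-1.51 ± 0.40, adjusted p = 0.146, with the block 1.31e-04). PDCD1LG2 had a value of -0.58 ± 0.30 (adjusted p = 0.559, with the block 0.00154) and MET of -0.12 ± 0.12. Of 24 ERK output genes 1 fell (1 up and 12 down adjusted over the list alone), by a median of -0.53, and the list kept its call with an estimated correlation (adjusted p = 0.0427). Of 25 genes of invasive growth 1 fell, PLAUR by -0.97 ± 0.17 (8 adjusted over the list alone), with adjusted p = 0.0176 with an estimated correlation and 0.0696 with the block as well. Of 26 ribosome biogenesis genes 0 passed over all genes (3 down adjusted over the list alone), with adjusted p = 0.0427 with an estimated correlation and 0.148 with the block as well. The chemokine list (1 down, 1 up and 4 down adjusted over the list alone) and the mesenchymal list (0, 2 down adjusted over the list alone) were called down and the mitosis list (0, 0 adjusted over the list alone) up with the preset correlation only, with adjusted p = 0.717, 0.717 and 0.950 with an estimated correlation.

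The comparison of crizotinib plus HGF with HGF called 64 genes, 17 up and 47 down, with 1744 of 17010 at an unadjusted p under 0.05. DESeq2 called 454, and 1632 passed with the replicate block. With 1 library left out the count was between 0 and 8. Against untreated cells, crizotinib plus HGF gave 0 genes with edgeR, 110 at an unadjusted p under 0.05 and 1 with DESeq2. SPRY4 had a value of 0.62 ± 0.33, FOSL1 of 0.35 ± 0.17, CD274 of 0.48 ± 0.39 and IRF1 of -0.19 ± 0.14 in that comparison. Camera with its preset correlation called 8 lists there, among them ERK output (median 0.17) and ribosome biogenesis (0.09) up and mitosis (-0.12) down, with no member passing over all genes or adjusted over the list alone. Their adjusted p = 0.233, 0.233 and 0.777 with an estimated correlation, and none of the 8 lists was called with one. Of the 469 genes changed by HGF all lay closer to untreated with crizotinib, and the median share of the HGF effect that remained was 0.222 (interquartile range 0.163 to 0.286). All 47 falls against HGF were of genes that HGF raised, and all 17 rises of genes that HGF lowered. These comparisons share libraries, so the same values were computed from simulated libraries in which crizotinib had no effect. There a median of 63.0 percent of the genes changed by HGF lay closer to untreated, the remaining share was 0.957 (0.943 to 0.971 over 20 simulations) and 0 genes were called in the opposite direction. The covariance of the HGF effect with the effect of adding crizotinib was -0.131 over all genes, against -0.0323 in the simulated libraries.

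**Figure D2:**
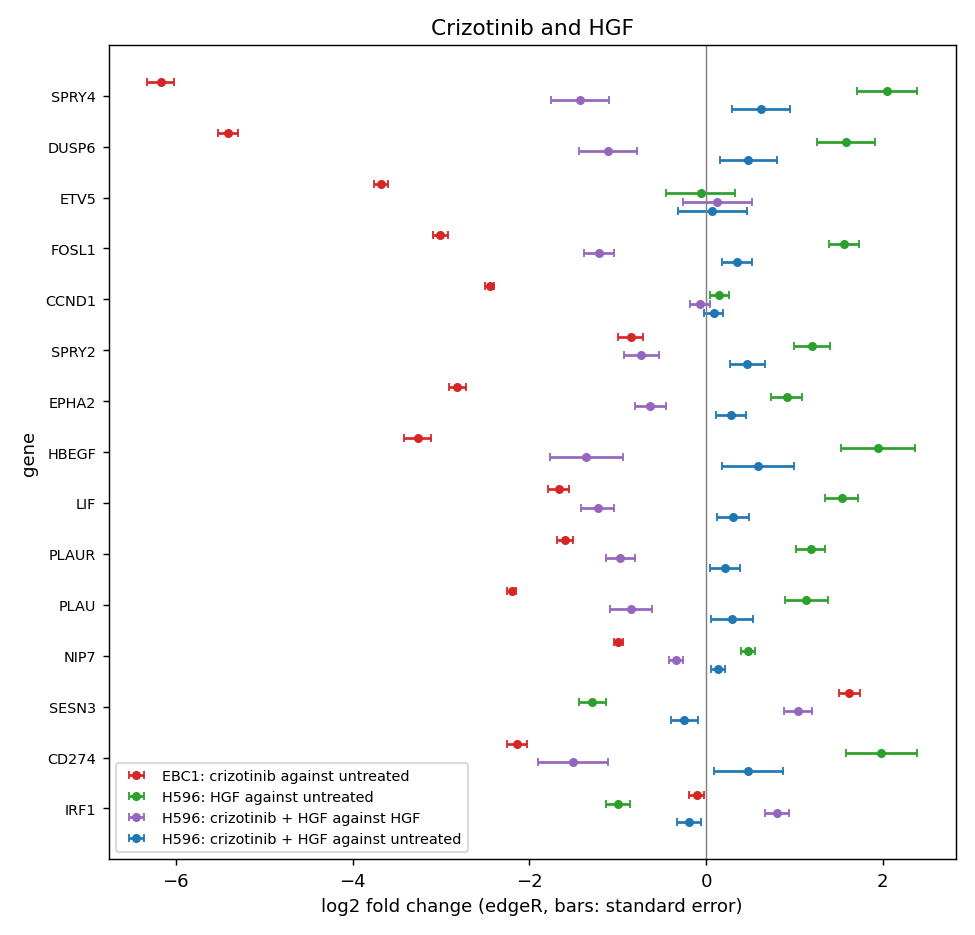
Log2 fold change (horizontal axis) of 15 genes with crizotinib in EBC1, with HGF in H596, with crizotinib plus HGF against HGF in H596 and with crizotinib plus HGF against untreated in H596, where points are edgeR estimates and bars their standard errors, n = 3 per group. SPRY4 was at -6.17 with crizotinib in EBC1, 2.05 with HGF in H596 and 0.62 with crizotinib plus HGF against untreated.

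Crizotinib effects were compared between EBC1, which was given no HGF, and H596, where HGF was present in both groups. Of 15081 genes tested in both, 33 fell in both lines, where independent calls would share 7.64 (Fisher's exact test, 1-sided, p = 1.39e-17), among them FOSL1, LIF, PLAUR and PTX3. A further 7 rose in both, where 2.15 were expected (same exact test, p = 0.00255), among them SESN3, KLHL24 and RAB30. DESeq2 gave 219 shared falls and 66 shared rises. A test of the difference itself called 497 of 18395 genes, 208 with a higher change in EBC1 and 289 with a lower one, and 2256 with the replicate block. ANGPTL4 (-4.97 ± 0.27), SPRY4 (-4.70 ± 0.49), DUSP6 (-4.26 ± 0.43), TNS4 (-4.17 ± 0.34), ETV5 (-3.76 ± 0.46) and EGR1 (-3.65 ± 0.76) fell further in EBC1. CCDC8 (2.58 ± 0.49), SLC5A3 (2.39 ± 0.31), CCNG2 (2.28 ± 0.23), a cyclin of growth arrest, ZIC2 (2.10 ± 0.27) and PRDM1 (2.09 ± 0.38) changed in the positive direction relative to H596. PDCD1LG2 (-2.53 ± 0.47, adjusted p = 0.00491) and IRF1 (-0.87 ± 0.17, adjusted p = 0.00526) differed, and CD274 had a difference of -0.58 ± 0.49 (adjusted p = 0.754).

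**Figure D3:**
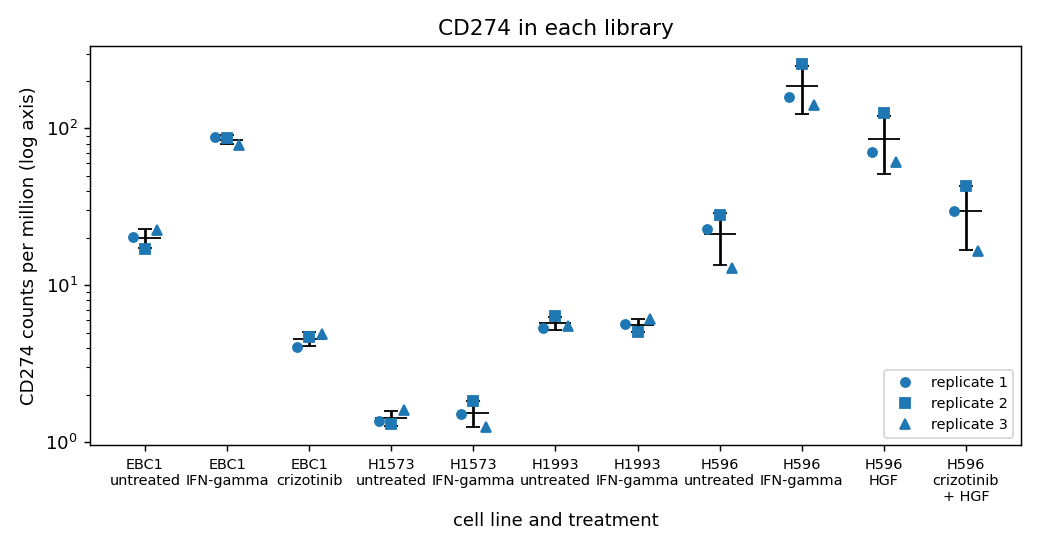
CD274 in CPM (log axis) in each of the 33 libraries by cell line and treatment, with a bar at the mean of 3 replicates and error bars of 1 SD. EBC1 averaged 20.03 untreated, 84.8 with interferon gamma and 4.54 with crizotinib, and H596 averaged 21.3 untreated, 185.5 with interferon gamma, 85.6 with HGF and 29.8 with crizotinib plus HGF.

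The untreated lines differed in most genes, 18212 of 18879 by a test over the 4 lines. MET was at 4522 ± 136 CPM in EBC1 and 5844 ± 87.2 CPM in H1993, and at 575.9 ± 18.1 CPM in H1573 and 336.0 ± 13.5 CPM in H596 (adjusted p = 9.14e-17). CD274 was at 20.03 ± 2.77 CPM in EBC1 and 21.3 ± 7.79 CPM in H596, and at 5.76 ± 0.55 CPM in H1993 and 1.43 ± 0.16 CPM in H1573 (adjusted p = 2.74e-08). Of MHC class I genes, B2M was at 2159 ± 35.7 and 1992 ± 73.4 CPM in EBC1 and H596 and at 356.8 ± 38.8 and 262.3 ± 6.13 CPM in H1573 and H1993, and HLA-B was at 470.6 ± 24.7, 926.7 ± 120, 79.5 ± 4.65 and 27.5 ± 1.0 CPM in EBC1, H596, H1573 and H1993, whereas the peptide transporter gene TAP1 was at 42.4 ± 1.93, 182.8 ± 60.1, 108.0 ± 10.5 and 31.2 ± 0.60 CPM. JAK2 was at 34.4 ± 6.83 CPM in H596, 5.86 ± 0.40 in EBC1, 3.62 ± 0.41 in H1573 and 2.56 ± 0.42 in H1993. JAK1 (117.3 to 279.0 CPM) and the receptor genes IFNGR1 (19.1 to 131.2 CPM) and IFNGR2 (24.3 to 95.2 CPM) were present in all 4 lines. The list of lung adenocarcinoma lineage genes was lowest in EBC1 (mean log2 CPM over 6 genes of the list 1.69 to 1.70 per untreated library, against 3.96 to 4.18 in H596, 4.16 to 4.24 in H1993 and 4.81 to 4.85 in H1573). The list of squamous lineage genes was highest in H596, labelled adenocarcinoma, and lowest in EBC1, labelled squamous (19 genes, 6.76 to 6.88 in H596, 3.33 to 3.52 in H1573, 2.41 to 2.46 in H1993 and 1.99 to 2.09 in EBC1). TP63, a squamous lineage factor, was at 88.7 ± 10.7 CPM in H596 and 0.159 ± 0.061 CPM in EBC1, and the squamous marker S100A2 at 1787 ± 415 and 35.2 ± 2.98 CPM. NKX2-1, a lung adenocarcinoma lineage factor, was at 3.59 ± 0.29 CPM in H1573, 3.29 ± 0.57 in H1993, 0.0640 ± 0.086 in H596 and 0.0262 ± 0.026 in EBC1, the last 2 values at or under the floor of 3 counts. Vimentin (VIM), a mesenchymal filament, was at 338.8 ± 20.6 CPM in EBC1 and 542.7 ± 159 CPM in H596, against 0.842 ± 0.41 CPM in H1573 and 11.7 ± 0.96 CPM in H1993.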

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

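Of the tests in this part, the splits were planned and all others were chosen only after the result was seen. The results listed here stood out as differences between cell lines. For interferon gamma 1609 genes differed among the 4 lines, 1083 between H1573 and EBC1, 973 between H1993 and EBC1, 391 between H596 and EBC1, 1024 between H596 and H1993 and 1079 between H1573 and H596, and for crizotinib 497 differed between EBC1 and H596. Of the genes followed throughout, CD274 (adjusted p = 3.82e-06), MET (0.0276), JAK2 (2.27e-08), IRF1 (2.79e-15), B2M (2.34e-07), HLA-B (3.84e-06) and HLA-C (0.0130) differed in their interferon gamma response. PDCD1LG2 (adjusted p = 0.00491) and IRF1 (0.00526) differed in their crizotinib effect.

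Whether any grouping of the libraries would do as well was tested with 100 splits drawn for each difference, the real one included. As many genes were called in 2 splits among the 4 lines (highest other 2990), in 2 for H1573 and EBC1 (1232), in 2 for H1993 and EBC1 (1046), in 2 for H596 and H1993 (1085), in 2 for H1573 and H596 (1467) and in 1 for the untreated lines (3400). In 16 splits H596 and EBC1 gave as many (4097) and in 8 the crizotinib effects did (1752), so chance was not excluded for these by this test. Splits that keep or exchange the labels of 1 line turn that line's own response into a difference. The splits left aside the replicate numbers, which pair the libraries of EBC1 and of H596, as did the real counts of 391 and 497, which were 1640 and 2256 with the replicate block. Of the splits with as many genes, 3 for H596 and EBC1 and 0 for crizotinib mixed the labels of both lines. For H1573 and H1993 all 100 splits gave as many genes as the real one, which was 0. Within a comparison there are 10 splits, too few for a share under 0.05. The real split gave the most genes and every other split 0 in EBC1 with interferon gamma (1 split, 3300 genes), H596 with interferon gamma (1 split, 1211), EBC1 with crizotinib (1 split, 5355), HGF (1 split, 469) and crizotinib plus HGF against HGF (1 split, 64). All 10 splits gave at least the 0 genes of H1573 (highest other 3) and of crizotinib plus HGF against untreated (highest other 0). In H1993 2 splits gave at least 6 genes, the real split with 6 and a split with 222. The cause of the 222 calls was not tested. That split parted the libraries of 1 replicate number only, while libraries sharing a number correlated at -0.0450 to 0.000994 in H1993. In the 1 simulated data set for this line 15.7% of the calls were false. That set held 200 changed genes, so its share need not hold for 6 or 222 calls.

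The pattern weighed first was that few genes answered interferon gamma in H1573 and H1993. Of 254 genes that rose at least 2-fold in both EBC1 and H596, 196 were tested in H1573 and 163 in H1993. Their median log2 fold change was -0.00488 in H1573 and 0.0183 in H1993, with upper quartiles of 0.0535 and 0.0876. For these genes a response as large as in EBC1 and H596, hidden by depth or spread, was excluded. A weaker response was not excluded by this test. The loss of a receptor or kinase transcript in both lines was excluded too, since the largest of the smallest folds between responding and other lines was 1.62, for JAK2, and these values say nothing of the proteins. Libraries labelled interferon gamma that come from untreated cells remain possible in H1573, where the interferon gamma list had an adjusted p of 0.987 with an estimated correlation. In H1993 that value was 0.138 and left the question open, as IRF9, NLRC5, PARP14 and APOL6 rose there.

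The next pattern was the higher level of interferon-stimulated genes in replicate 2 of H596. RNA carried over from cells given interferon gamma was excluded, since replicate 2 showed a median share of 0.0514 of the interferon gamma rise of core genes and of 1.15 for type I interferon genes. RNA of another cell type was left open, as its markers were at 0.830 of the mean of replicates 1 and 3 but at 1.26 to 1.48 times replicate 1 and 0.501 to 0.679 times replicate 3 over the 4 groups. Type I interferon activity in these cultures was left open. The type I interferon genes were higher in replicate 2 by a median log2 of 1.73, but that rise is the pattern itself and cannot test its cause. IRF1 was higher by only 0.04 and CIITA by 0.30. The 29 interferon gamma core genes outside the type I list were higher as well, by a median of 0.95.

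The last pattern was that CD274 fell with crizotinib in EBC1 and rose with HGF in H596. An interferon response to HGF that raises IRF1 was excluded, as IRF1 had a log2 fold change of -0.998 with HGF. A type I interferon response could not be excluded by IRF1. In replicate 2 of H596 type I interferon genes were higher by a median log2 of 1.73 and IRF1 by 0.04. With HGF the mean log2 CPM of the 37 type I interferon genes was 5.222, 7.145 and 5.532 in replicates 1, 2 and 3. In untreated cells it was 5.041, 6.988 and 6.123. These genes were slightly higher with HGF in replicates 1 and 2 and lower in replicate 3, which argues against a type I interferon response to HGF in all replicates. A difference in depth or scaling factor was excluded, as the effective sizes (total count times scaling factor) of treated and untreated libraries differed by a log2 of at most 0.230 in EBC1 and 0.322 in H596, where the change of CD274 less 2 SE was 1.91 and 1.18. Control of CD274 by signalling from MET would be consistent with both changes (-2.14 ± 0.11 and 1.99 ± 0.40) and with the lower level of CD274 when crizotinib was added to HGF (29.8 against 85.6 CPM, -1.51 ± 0.40, adjusted p = 0.146, with the block 1.31e-04, with DESeq2 0.00524), but crizotinib inhibits other kinases as well and no library here separates it from other effects of the treatments.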

How the results depend on the processing

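Depth limited genes under 0.0684 to 0.115 CPM, and 3 libraries per group limited small changes. The scaling and the filter of 1 CPM in 3 libraries left all 17 counts of called genes within 1.5-fold, DESeq2 left 10 of 17 and the absence of a filter 15 of 17. No named gene turned its direction with a call on both sides. Over the 8 comparisons, 166 tests of named genes passed only with the replicate block, 785 stayed on the same side and none was lost, and of the single list tests 26 became stronger and 1 weaker with it. Where a value moved and no reason is given, the cause was not tested.

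With the replicate number as a block, which removes differences between replicates, the counts were 5594 for interferon gamma in EBC1, 3359 in H596, 1 in H1573 and 111 in H1993 (the last 2 not paired). They were 7741 for crizotinib in EBC1, 3340 for HGF and 1632 for crizotinib plus HGF against HGF. The differences gave 3965 among the 4 lines, 2438 for H1573 and EBC1, 2321 for H1993 and EBC1, 1640 for H596 and EBC1, 2756 for H596 and H1993, 2787 for H1573 and H596 and 2256 for crizotinib. With the block and the preset correlation, camera called 8 lists in H1573, 6 in H1993 and 12 for crizotinib plus HGF against HGF. It gave shared interferon gamma responses of 1257 up and 701 down and shared crizotinib effects of 628 down and 387 up, all 4 chosen after seeing the data.

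DESeq2 called 3 genes in H1573, 13 in H1993, 1188 with HGF, 454 for crizotinib plus HGF against HGF and 1 against untreated, 602 for H596 and EBC1 and 854 for the crizotinib difference. It gave 234 shared falls with interferon gamma and 219 shared falls and 66 shared rises with crizotinib. Without a filter H1573 had 7 genes, H1993 had 85 and the shared crizotinib rises were 13. At 2-fold or more the shared interferon gamma response was 254 up and 7 down and the shared crizotinib effect 7 down and 2 up. A model of only the 2 groups compared gave 757 for interferon gamma in H596 and 0 for crizotinib plus HGF against HGF, and 1 model of all 33 libraries gave 2595, 952, 2351 for HGF and 0 for H1993. Without replicate 2 of H596, chosen after seeing the data, the counts were 431 with interferon gamma, 14 with HGF and 0 for crizotinib plus HGF against HGF, with fewer samples.

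Lists called with an estimated correlation numbered 0 in H1573, 0 in H1993, 3 for interferon gamma in H596, 3 for crizotinib in EBC1, 3 for HGF, 3 for crizotinib plus HGF against HGF and 0 against untreated. With fry they numbered 0, 0, 6, 15, 3, 3 and 0.

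With 1 library left out, counts ranged from 0 to 2 in H1573 (1 without untreated replicate 1, 2 without interferon gamma replicate 1) and from 2 to 41 in H1993 (11 without untreated replicate 1, 2 without interferon gamma replicate 2, 3 without untreated replicate 3, 41 without interferon gamma replicate 3). For interferon gamma in H596 they ranged from 766 to 1151 (766 without untreated replicate 1, 805 without interferon gamma replicate 2, 793 without untreated replicate 3). For HGF they ranged from 90 to 254, with 254, 163 and 90 without untreated replicates 1, 2 and 3 and 248, 114 and 171 without HGF replicates 1, 2 and 3. For crizotinib plus HGF against HGF they ranged from 0 to 8, with 8, 3 and 2 without HGF replicates 1, 2 and 3 and 1, 3 and 0 without crizotinib plus HGF replicates 1, 2 and 3. The difference between H596 and EBC1 ranged from 282 to 611 (611 without H596 interferon gamma replicate 1) and the crizotinib difference from 308 to 438 (328 without EBC1 untreated replicate 1, 308 without EBC1 crizotinib replicate 2). The share of the HGF effect remaining ranged from 0.161 to 0.284 (0.284 without untreated replicate 1, 0.161 without crizotinib plus HGF replicate 2, 0.277 without crizotinib plus HGF replicate 3), and the replicates gave 0.188, 0.268 and 0.226 with an SD of 0.0401.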

Other observations

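Both tests in this part were chosen only after levels of the untreated lines were seen. EBC1 lacked transcripts of neighbouring genes that the other lines expressed. On chromosome 22, from 50263713 to 50475024, MAPK11, a stress kinase, PLXNB2, a semaphorin receptor, DENND6B and PPP6R2 had 0 counts in the 3 untreated EBC1 libraries and SBF1 had 1, while PLXNB2 was at 416, 311 and 374 CPM and SBF1 at 168, 170 and 76.8 CPM in H1573, H1993 and H596. CEACAM5 and CEACAM6, adhesion molecules of epithelia, on chromosome 19, and PRMT6 and VAV3, on chromosome 1, were the other neighbours near 0 in EBC1. In H1993 the neighbours near 0 were the chromatin remodeller gene SMARCA1 (0 counts) and the phosphatase gene OCRL (1 count) on the X chromosome, KIRREL1 and the DNA sensor gene IFI16 on chromosome 1, and ZNF304, ZNF548, ZNF134 and ZNF551 on chromosome 19. IFI16 was at 0.0968 CPM in H1993 and at 29.9, 5.73 and 231 CPM in EBC1, H1573 and H596.

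The loss of a shared stretch of chromosome could leave such runs. In EBC1 39 of 9623 genes at 5 CPM or more in the other lines were near 0 and formed 6 neighbouring pairs, where random draws gave at most 3 (permutation p = 1e-04, the smallest possible with 10000 draws). In H1993 35 genes formed 4 pairs, where draws gave at most 2 (permutation p = 1e-04, the smallest possible). In H1573 11 genes near 0 formed 0 pairs (permutation p = 1), and in H596 5 genes formed 0 pairs (permutation p = 1). Silencing of neighbouring genes would leave the same runs, and DNA was not analysed here.

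MET was highest in EBC1 and H1993, lines known for amplified MET, and a raised stretch of chromosome could lift its neighbours as well. In EBC1 the 7 expressed genes within 2 Mb of MET had a median log2 of 2.13 over H1573 and H596, and a share of 0.00156 of 11552 runs of as many neighbouring genes reached it. H596 had the lowest level of all 7, which lifts the median, and 5 of the 7 were higher in EBC1 than in both H1573 and H596. CAV1, a caveola protein, was at 4963 CPM in EBC1, 2198 in H1573, 930.1 in H1993 and 582.9 in H596, and LSM8 was at 211.5, 24.58, 131.1 and 24.55 CPM, whereas ST7 (156.6 against 193.2 CPM) and MDFIC (113.4 against 159.7 CPM) were lower in EBC1 than in H1573. In H1993 the median was 0.77 and the share 0.117, which leaves the question open there. TES was at 674.0 CPM against 277.5 in H1573 and 55.45 in H596, but CAV1, CAPZA2, ST7 and MDFIC were lower than in H1573, and 3 of the 7 were higher than in both lines.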
